A study of Mus musculus with 18 samples.

How the data were processed

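RNA of RAW cells was amplified with NuGEN's Ovation system and hybridised to 1-colour Affymetrix mouse arrays, per the labels' protocols. The 18 arrays were grouped by the labels into medium at 0 h (2 arrays) and, at 1, 3, 7 and 22 h, medium, R848, R848+apilimod and R848+API09 (1 array each). The labels give R848 at 0.1 mM, a high dose for such an agonist that may be an error of unit, and each compound at 1 uM. The deposited values are intensities on a linear scale, 1 per probe set and array. They were read as already summarised and normalized between arrays by the authors, since the median intensity differed little between arrays (17.5 to 19.2); no label says so. The submitters' processing notes name limma, with no version and no role. The background correction, the summarisation and the normalization method are not given in the sources used here. That the values are linear was read from the values themselves, which are all above 0 and reach 22099 at most.

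Of the 45101 probe sets, 64 were control probe sets, 34958 were listed with 1 gene symbol, 932 with several and 9160, control probe sets aside, with none. Control probe sets with a symbol are counted in both groups. Symbols were updated through Entrez identifiers, which matched the gene table for 34754 of the probe sets with 1 symbol. The others kept the symbol of the annotation, and probe sets with several symbols were not used. A probe set was kept when its intensity was above the median of all values (18.1) on at least 3 arrays, which left 24154 probe sets, 21361 of them with 1 symbol. Each gene was represented by its probe set with the highest mean, which gave 12257 genes, 5456 of them with more than 1 kept probe set. Values were tested as log2 of the intensity plus 16. The added 16 compresses dim genes towards 0 difference. How much background the deposited values hold is not known. Of 20 fixed genes, 17 were among the genes tested; the others were not analysed here.

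Tests were made in R 4.3.3 with limma 3.58.1, with moderated variances and Benjamini-Hochberg adjustment, and genes were called at an adjusted p of 0.05, two-sided. The fit over all hours had a term for each arm and a block for each hour over the 18 arrays. It tests differences held over 1 to 22 h, and effects that change with time add to its spread. The fit within hours gave each arm and hour its own mean, except that the R848 and R848+API09 arrays of an hour shared 1 mean and so supplied, with the 2 medium arrays at 0 h, the estimate of the spread. The lone R848+apilimod and medium arrays are assumed to vary like these pairs. Because R848+API09 arrays served as controls there, a difference of API09 from R848 alone enlarges the spread and is not itself tested within an hour. The median standard error was 0.103 in the fit over hours and 0.110 within hours. Intervals are 95% intervals from the same fits.

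Gene lists, 34 in all, were fixed before the data were examined, and the 30 with at least 5 measured genes were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. The preset correlation takes genes of a list to vary nearly independently, while the estimate is taken from the residuals of the fit. The camera tests within hours were added after the values were seen. List medians were also set against 10000 random lists of the same size drawn from 20 bins of mean expression. Genes named in the text were chosen by a rule fixed before the data were examined. For each contrast of arms it takes the 8 largest rises and the 8 largest falls among called genes of the same sign at all 4 hours. For each comparison within an hour it takes the 5 largest of each sign among called genes. From each list described it takes up to 4 members with the largest absolute difference in the contrast over all hours, and it adds the fixed genes. Which hours to print for a named gene, and which lists to describe, was chosen after the values were seen. No gene passed for the compounds over all hours, so the first part named genes only for R848 against medium.

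The code was tested on simulated data with 200 of 12257 genes changed. Within hours, 56.7% to 74.6% of the genes changed by 0.5 log2 units were recovered, 98.5% to 100% of those changed by 1 and 100% of those changed by 2. In the fit over all hours the shares were 58.2% to 73.1%, 91.0% to 97.0% and 100%. Of 12057 unchanged genes, 6 to 16 were called. The simulation had constant effects and independent arrays.

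The alternatives tried were quantile normalization of the deposited values, centring of each array on its median, no filter and a stricter filter (above the 75th percentile), and the mean over the probe sets of a gene. Others were variances with a trend and robust estimation, a minimum absolute log2 difference of 1, and a pseudocount of 1. Arrays were also regrouped: either medium array at 0 h left out, each hour left out, each R848+API09 array left out, the arms compared alone, no hour block, either control array alone, and the 6 medium arrays as 1 group. The R848+API09 array at 22 h left out of the fits over all hours, the overlaps within single hours, and the lists at 22 h with R848 alone as the control, were added after the values were seen. Overlaps of called genes were compared with the product of the list sizes over the genes tested. Figures were drawn from the tables of results.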

Results

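RAW cells, a mouse macrophage-like cell line, were left in medium or stimulated with R848, a small molecule that activates Toll-like receptor 7 in mouse cells. Stimulated cells received R848 alone (0.1 mM in the labels, a high dose that may be an error of unit), with apilimod at 1 uM or with API09 at 1 uM. Apilimod is an inhibitor of the lipid kinase PIKfyve that was first described as a blocker of IL-12 and IL-23 production. Per the series design API09 is its inactive analog. Expression was measured on 18 Affymetrix mouse arrays, with 2 arrays of medium at 0 h and 1 array per arm at 1, 3, 7 and 22 h. The arrays held 45101 probe sets, of which 12257 genes entered the tests. The number of arrays limits the precision, since each arm and hour after 0 h had 1 array and the labels do not say that arrays came from separate cultures. The p values therefore measure the spread between these arrays, which may be technical. The R848 and R848+API09 arrays of an hour served as 2 control arrays (R848 controls), and their difference was the main source of the spread in the fits within an hour.

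Most arrays were alike in brightness, but the stimulated arrays at 22 h were dimmer at the upper quartile, the R848+API09 array most of all. The median intensity ran from 17.5 to 19.2 over the 18 arrays. At 22 h the upper quartile was 87.0 on the R848+API09 array, 100.9 on the R848+apilimod array and 103.6 on the R848 array. It was 110.5 to 118.6 on the others. The median log2 level over the genes tested was 7.03 on the R848+API09 array at 22 h against 7.19 to 7.37 on all other arrays. The control probe sets for 18S ribosomal RNA had a mean log2 intensity of 7.94 to 9.36 on the 6 medium arrays. The value was 10.53 on the R848+API09 array at 22 h, 10.14 on the R848+API09 array at 7 h and 9.45 on the R848+apilimod array at 22 h.

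The first comparison asked how R848 changed the cells over time. At 1 h the largest rise was that of Nfkbiz, an inducible regulator of NF-kB target genes, by 4.27 ± 0.09 (log2 difference and its standard error, 2 control arrays against 1 medium array). Next came the neutrophil-attracting chemokine Cxcl2 by 4.17 ± 0.15, the NF-kB feedback inhibitor Tnfaip3 by 4.02 ± 0.14 and Tnf by 3.82 ± 0.11. Txnip, which encodes a thioredoxin-binding protein, had the largest fall at -1.14 ± 0.09. By 3 h Il1b was higher by 7.25 ± 0.17 and Il1a by 5.83 ± 0.18, which encode the interleukin-1 cytokines, and the chemokine gene Ccl5 by 5.09 ± 0.10. At 7 h Il1b reached 7.93 ± 0.17, the granulocyte growth factor Csf3 7.17 ± 0.12 and the cytokine signalling inhibitor Socs3 6.63 ± 0.10. At 22 h the largest rises were of S100a8 by 8.11 ± 0.12, Lcn2 by 7.75 ± 0.13, the prostaglandin synthase gene Ptgs2 by 7.17 ± 0.13 and the acute-phase gene Saa3 by 6.79 ± 0.11. Hpgd, whose product degrades prostaglandins, was lower (-3.64 ± 0.18 at 7 h and -3.64 ± 0.18 at 22 h), as was the oxysterol receptor gene Gpr183 (-3.12 ± 0.10 at 3 h and -3.41 ± 0.10 at 22 h). The fractalkine receptor gene Cx3cr1 fell by 3.05 ± 0.22 at 22 h, and Plau, which encodes urokinase, fell by 3.38 ± 0.15 at 7 h.

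Gene lists were counted at each hour. Of 15 immediate-early genes, 13 rose at 1 h. Dusp1 was at 3.53, Zfp36 at 3.30 and Dusp2 at 2.93 (15 adjusted over the list alone; camera, adjusted p = 4.62e-97, and adjusted p = 0.00955 with an estimated correlation). At 3, 7 and 22 h 8, 10 and 8 of them were higher and 1, 2 and 4 lower. Of 16 inflammatory cytokine genes, 7 rose at 1 h, 13 at 3 h and 15 at 7 h (9, 13 and 15 adjusted over the list alone). The camera test of this list gave adjusted p = 5.32e-26, and adjusted p = 0.0157 with an estimated correlation at 3 h and adjusted p = 1.56e-20, and adjusted p = 0.0349 with an estimated correlation at 7 h. Of 13 chemokine genes, 11 rose at 3 h and 12 at 7 h (12 and 12 adjusted over the list alone). Among them were Ccl4 at 4.20 and Ccl2 at 2.17 at 3 h (adjusted p = 1.06e-21, and adjusted p = 0.0152 with an estimated correlation for the list). All 16 NF-kB response genes rose at 3 h (16 adjusted over the list alone; adjusted p = 4.42e-32, and adjusted p = 0.0152 with an estimated correlation), including the costimulatory receptor gene Cd40 at 4.35. Of 22 interferon-stimulated genes, 0 passed at 1 h, 21 rose at 3 h and 22 at 7 h (0, 21 and 22 adjusted over the list alone). The antiviral gene Ifit1 was at 4.32 and Ifit3 at 2.89 at 3 h. The call for this list at 7 h was lost with an estimated correlation (adjusted p = 1.52e-22, and adjusted p = 0.0953 with an estimated correlation). Cell cycle genes fell: 11 of 16 DNA replication genes at 3 h and 16 at 7 h (16 and 16 adjusted over the list alone). So did 13 of 22 mitosis genes at 3 h and 22 at 7 h (19 and 22 adjusted over the list alone). At 7 h the replication licensing gene Mcm7 was at -1.49 ± 0.08 and the spindle gene Nusap1 at -1.44 ± 0.09. Camera gave adjusted p = 1.57e-12, and adjusted p = 0.130 with an estimated correlation for replication and adjusted p = 2.46e-14, and adjusted p = 0.221 with an estimated correlation for mitosis. At 22 h 16 of 21 oxidative phosphorylation genes were lower (16 adjusted over the list alone; adjusted p = 0.00444, and adjusted p = 0.544 with an estimated correlation). Of the Toll-like receptor genes, Tlr7, which encodes the receptor for R848, fell by 2.02 ± 0.12 at 22 h.

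Of the 5 genes of the IL-12 family list, 3 entered the tests (Il12b, Il23a and Ebi3), too few for camera. Il12a and Il27 did not enter them. Il12b, which encodes the subunit shared by IL-12 and IL-23, rose by 0.95 ± 0.12 at 3 h and 0.69 ± 0.12 at 7 h. Ebi3, a subunit of IL-27 and IL-35, rose by 2.24 ± 0.10 at 7 h. The signal of Il12b was dim. On all 6 medium arrays it was below the filter level of 18.1, and at 3 h it was 10.5 on medium and 36.7 and 33.8 on the 2 control arrays. The size of its change therefore depends on the value added before the log: with 1 in place of 16, Il12b for R848 at 3 h was 1.66 and for apilimod at 3 h -1.82. Il6 rose by 3.66 ± 0.10, Il10 by 5.04 ± 0.09 and Nos2, the inducible nitric oxide synthase gene, by 1.19 ± 0.19 at 7 h. In all, R848 changed 85 genes at 1 h (77 higher and 8 lower), 1890 at 3 h (767 and 1123), 3654 at 7 h (1391 and 2263) and 5581 at 22 h (2025 and 3556) at an adjusted p of 0.05. Among genes changed by at least 1 log2 unit the balance was the other way at 3 h (256 higher and 108 lower) and 7 h (386 and 310), and at 22 h it was 319 and 530. With the values quantile normalized, the split at 22 h turned to 3253 higher and 2965 lower, so the balance of higher and lower calls at 22 h depended on the scaling. Without the R848+API09 array at 22 h, the spread was smaller and the counts were 128 at 1 h and 3028 at 3 h.

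**Figure D1:**
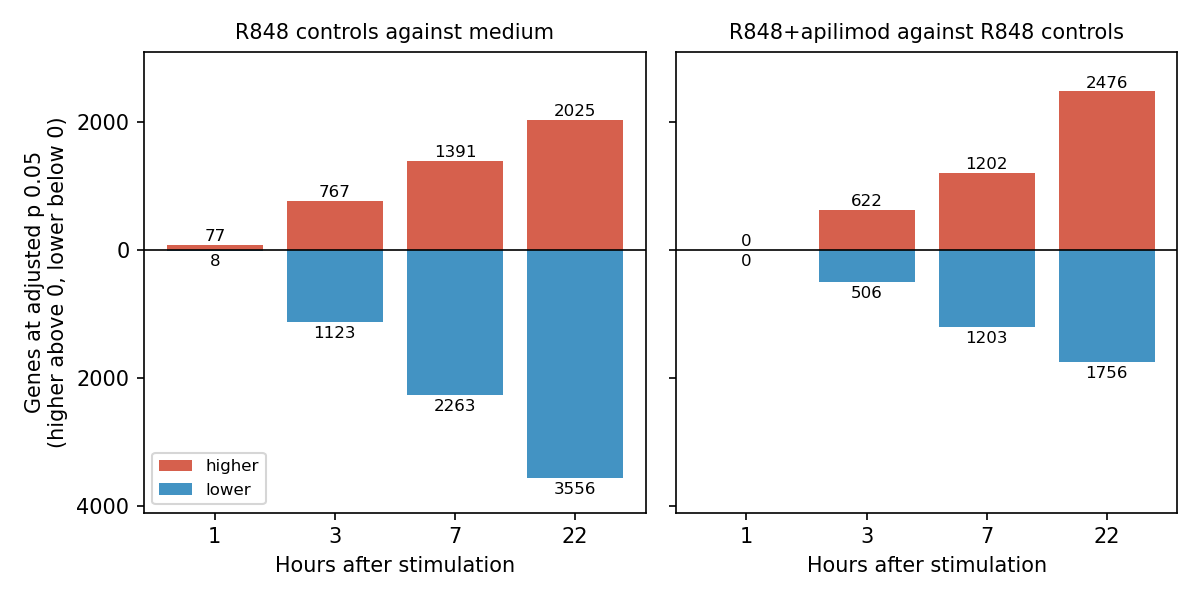
Number of genes called at an adjusted p of 0.05 (y axis, genes higher above 0 and genes lower below 0) at each hour after stimulation (x axis), for the R848 controls against medium (left) and for R848+apilimod against the R848 controls (right). The counts for apilimod go from 0 at 1 h to 2476 higher and 1756 lower at 22 h.

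A fit over all 4 hours with the hour as a block, which asks for a difference held through the course, called 124 genes for R848 alone against medium (99 higher and 25 lower, 4 arrays per arm). Cxcl2 was higher by 5.65 ± 0.38, Il1b by 5.64 ± 0.92, Socs3 by 5.16 ± 0.47, Nfkbiz by 5.02 ± 0.22, Ptgs2 by 4.79 ± 0.63, Csf3 by 4.59 ± 0.96, Il1a by 4.17 ± 0.79 and Saa3 by 3.91 ± 0.84. Lower were Gpr183 (-2.38 ± 0.49), Cytip, a regulator of leukocyte adhesion (-1.66 ± 0.36), and the DNA replication gene Gins3 (-1.09 ± 0.16). The camera test called the inflammatory cytokines (adjusted p = 1.57e-14, and adjusted p = 0.0210 with an estimated correlation), chemokines (adjusted p = 6.19e-13, and adjusted p = 0.0238 with an estimated correlation), NF-kB response genes (adjusted p = 4.68e-19, and adjusted p = 0.0210 with an estimated correlation) and immediate-early genes (adjusted p = 9.51e-11, and adjusted p = 0.0279 with an estimated correlation), all higher, and fry called all 4 as well. Camera at the preset correlation called other lists too. Among these, only the regulators of the IL-12 genes stayed called with an estimated correlation (adjusted p = 0.0210). The calls lost included interferon-stimulated genes, higher (adjusted p = 9.85e-13, and adjusted p = 0.217 with an estimated correlation). Those of DNA replication genes (3.22e-05 and 0.4205) and mitosis genes (2.16e-04 and 0.660), both lower, were lost as well. With quantile normalization the split of called genes was 132 higher and 71 lower. The count and its balance rested on single hours: it was 1162 without the 1 h arrays (456 higher and 706 lower). Without the 3 h arrays it was 14, without the 7 h arrays 17 and without the 22 h arrays 43. The count was 49 without either of the medium arrays at 0 h. Those 2 arrays enter only the estimate of the spread, not the difference between the arms.

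The second comparison asked what apilimod changed in R848-stimulated cells. At 1 h no gene passed (limma, 0 of 12257 genes; 165 at an unadjusted p under 0.05, smallest adjusted p 0.114). In the simulation of this comparison 604 of 12057 unchanged genes had an unadjusted p under 0.05. The spread may thus be too wide to show a small effect. Against R848+API09 alone at 1 h, Il1b was at -1.12 ± 0.19 and Atf3 at 0.47 ± 0.16, and neither passed. Gpnmb (-0.08 ± 0.11) and Il6 (-0.01 ± 0.12) differed little there. The R848 and R848+API09 arrays lay apart for Il1b at that hour. An effect at 1 h is not excluded. At 3 h the largest rise with apilimod (1 array against 2 R848 control arrays) was of Tent5c, which encodes a poly(A) polymerase, by 4.76 ± 0.14. Next were the kinase gene Sgk1 by 4.49 ± 0.13 and the membrane protein gene Lhfpl2 by 4.11 ± 0.10. Then came Fnip2, a partner of the lysosomal regulator folliculin, by 3.46 ± 0.10. The largest falls were of Il1b at -5.77 ± 0.17 and Il1a at -4.19 ± 0.18. Next were the G-protein regulator gene Rgs16 at -3.54 ± 0.13 and the heat shock gene Hspa1b at -3.47 ± 0.14. At 7 h Tent5c was higher by 4.69 ± 0.14, the interleukin-7 receptor gene Il7r by 4.29 ± 0.22 and the fatty acid-binding protein gene Fabp4 by 4.14 ± 0.16. At that hour the lowest differences were those of Serpinb2, a plasminogen activator inhibitor gene, at -5.16 ± 0.17, the matrix gene Tnc at -4.77 ± 0.14 and the transcription factor gene Maf at -4.65 ± 0.14. At 22 h Atp6v0d2, a vacuolar ATPase subunit gene, was higher by 4.21 ± 0.20, Il7r by 3.83 ± 0.22 and Fabp3 by 3.30 ± 0.14. The cytokine gene Il33 fell by 5.90 ± 0.10 at 22 h. S100a8 (-5.71 ± 0.12), Serpinb2 (-5.38 ± 0.17) and the metalloproteinase inhibitor gene Timp1 (-5.07 ± 0.18) were also lower.

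Cytokine genes moved in both directions. Il12b was lower with apilimod (-1.02 ± 0.12 at 3 h and -0.68 ± 0.12 at 7 h), and its difference at 22 h was 0.01 ± 0.12, which did not pass. Ebi3 fell by 1.43 ± 0.10 at 7 h. Il23a, which encodes the other subunit of IL-23, was higher by 0.72 ± 0.10 at 22 h. Il6 was lower at 3 h (-1.45 ± 0.10), 7 h (-2.25 ± 0.10) and 22 h (-0.91 ± 0.10). Il10, which encodes an anti-inflammatory cytokine, was higher by 1.37 ± 0.09 at 3 h and lower at 7 h (-3.86 ± 0.09) and 22 h (-4.59 ± 0.09). Tnf was higher by 1.15 ± 0.11 at 7 h, and Il1b stayed lower at 7 h (-5.05 ± 0.17) and 22 h (-2.77 ± 0.17). Ccl5 was lower at 3 h (-2.69 ± 0.10), 7 h (-2.99 ± 0.10) and 22 h (-1.30 ± 0.10). Cxcl10, an interferon-induced chemokine gene, was lower at 3 h (-1.83 ± 0.11) and 7 h (-1.47 ± 0.11) and higher by 0.93 ± 0.11 at 22 h. Ifnb1, the interferon beta gene, and Ptgs2 were lower at 3 h (-0.64 ± 0.13 and -1.24 ± 0.13), and Nos2 was higher by 0.67 ± 0.19 at 7 h. With R848+API09 alone as the control Nos2 at 7 h was 0.49 ± 0.22 (95% interval -0.00 to 0.98) and did not pass (adjusted p = 0.194). Of 16 inflammatory cytokine genes, 5 were higher and 7 lower at 3 h, 4 and 9 at 7 h, and 2 and 6 at 22 h (5 and 8, 4 and 9, and 3 and 6 adjusted over the list alone).

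**Figure D2:**
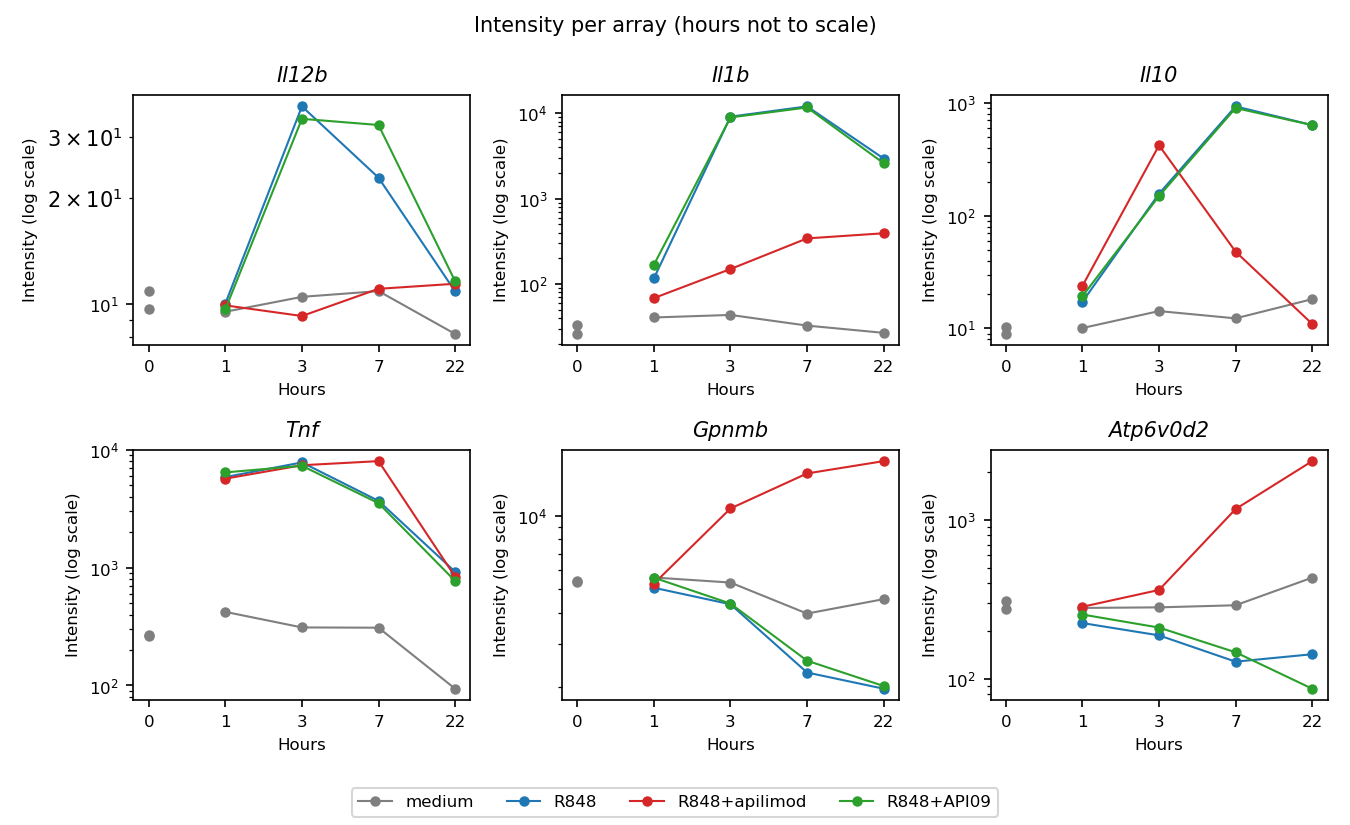
Deposited intensity (y axis, log scale) against hours after stimulation (x axis) for Il12b, Il1b, Il10, Tnf, Gpnmb and Atp6v0d2. Each point is 1 array, and lines join the arrays of an arm. The R848 and R848+API09 arrays lie apart for Il12b at 7 h, Il1b at 1 h and Atp6v0d2 at 22 h and closer elsewhere. The R848+apilimod arrays lie below them for Il1b from 3 h and above them for Gpnmb from 3 h. At 1 h the R848+apilimod array lies below the R848+API09 array for Il1b.

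Lysosomal genes rose with apilimod. Of 16 vacuolar ATPase subunits, which form the proton pump that acidifies lysosomes, 10 rose at 3 h, 15 at 7 h and 15 at 22 h and 0 fell (13, 15 and 15 adjusted over the list alone). Atp6v0d2 was higher by 0.82, 2.96 and 4.21 at 3, 7 and 22 h, Atp6v1d by 1.53 and Atp6v1a by 1.22 at 7 h. Of 34 lysosomal genes, 12 rose at 3 h, 25 at 7 h and 23 at 22 h, and 1, 1 and 2 fell (21, 25 and 24 rose adjusted over the list alone). Gpnmb, a lysosomal glycoprotein gene, rose by 1.29 ± 0.10, 2.61 ± 0.10 and 3.05 ± 0.10, the alpha-galactosidase gene Gla by 2.48 ± 0.08 at 7 h and the lysosomal chloride transporter gene Clcn7 by 2.11 ± 0.12 at 7 h. At 7 h the camera test gave adjusted p = 1.30e-13, and adjusted p = 0.114 with an estimated correlation for the pump and adjusted p = 1.30e-13, and adjusted p = 0.114 with an estimated correlation for the lysosomal genes, so both calls were lost with the estimated correlation. The medians of both lists at 22 h lay above all 10000 random lists matched on expression, with percentiles of 100. With R848 alone as the control at 22 h, 13 pump subunits and 20 lysosomal genes rose and the percentiles were also 100. Of 24 autophagy genes, 7 rose and 1 fell at 7 h and 11 rose at 22 h, with the receptor gene Sqstm1 at 1.43 at 7 h (7 at 22 h with R848 alone as the control; 7 and 11 rose adjusted over the list alone; adjusted p = 0.00396, and adjusted p = 0.678 with an estimated correlation at 22 h). Pikfyve, which encodes the kinase that apilimod inhibits, was higher by 0.57 ± 0.15 at 3 h and 0.60 ± 0.15 at 7 h. Tfeb, a transcription factor gene for lysosomal genes, was higher by 0.35 ± 0.08 at 3 h, and its differences at 7 h (-0.08 ± 0.08) and 22 h (0.05 ± 0.08) did not pass. With R848+API09 alone as the control, which has a larger standard error, these 3 calls were lost: Pikfyve was 0.60 ± 0.18 (95% interval 0.21 to 0.99) at 3 h and 0.50 ± 0.18 (95% interval 0.12 to 0.89) at 7 h, and Tfeb was 0.32 ± 0.10 (95% interval 0.11 to 0.54) at 3 h (adjusted p = 0.0724, 0.0813 and 0.0825). With R848 alone as the control Pikfyve at 3 h was 0.54 and did not pass either. The call of Atp6v0d2 at 3 h was lost with R848+API09 alone (0.74).

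Sterol and lipid synthesis genes were mostly higher at 7 h and mostly lower at 22 h. Of 20 cholesterol synthesis genes, 14 rose at 3 h and 18 at 7 h, while 2 were higher and 11 lower at 22 h (16, 19, and 2 and 11 adjusted over the list alone). Insig1, a sterol feedback regulator, was higher by 1.83 at 3 h, and the enzyme genes Mvd by 2.13 and Dhcr7 by 1.68 at 7 h. The camera test gave adjusted p = 1.72e-21, and adjusted p = 0.114 with an estimated correlation at 7 h. Of 12 fatty acid synthesis genes, 10 rose at 7 h, with the acetyl-CoA synthetase gene Acss2 at 1.68 and the desaturase gene Scd1 at 1.33. At 22 h 2 were higher and 7 lower (10, and 3 and 7 adjusted over the list alone; adjusted p = 1.67e-08, and adjusted p = 0.114 with an estimated correlation at 7 h). The cholesterol export genes Abca1 and Abcg1, targets of the oxysterol receptor LXR, were at -3.28 ± 0.15 and -2.41 ± 0.09 at 7 h, when 3 of 8 LXR target genes were lower (4 adjusted over the list alone; adjusted p = 0.00481, and adjusted p = 0.119 with an estimated correlation). Of 23 amino acid response genes, which ATF4 controls under amino acid shortage, 12 rose at 3 h and 21 at 7 h. At 22 h 6 were higher and 6 lower (19, 21, and 7 and 6 adjusted over the list alone). The phosphatase regulator gene Ppp1r15a was higher by 2.16 and Ddit3 by 1.25 at 7 h, and the test gave adjusted p = 8.64e-13, and adjusted p = 0.114 with an estimated correlation. Of 10 oxidative stress response genes, 6 rose at 7 h (7 adjusted over the list alone; adjusted p = 1.28e-04, and adjusted p = 0.262 with an estimated correlation), with the heme oxygenase gene Hmox1 at 1.89 ± 0.15. The stress transcription factor gene Atf3 was higher by 1.59 ± 0.14, 2.33 ± 0.14 and 0.90 ± 0.14 at 3, 7 and 22 h.

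**Figure D3:**
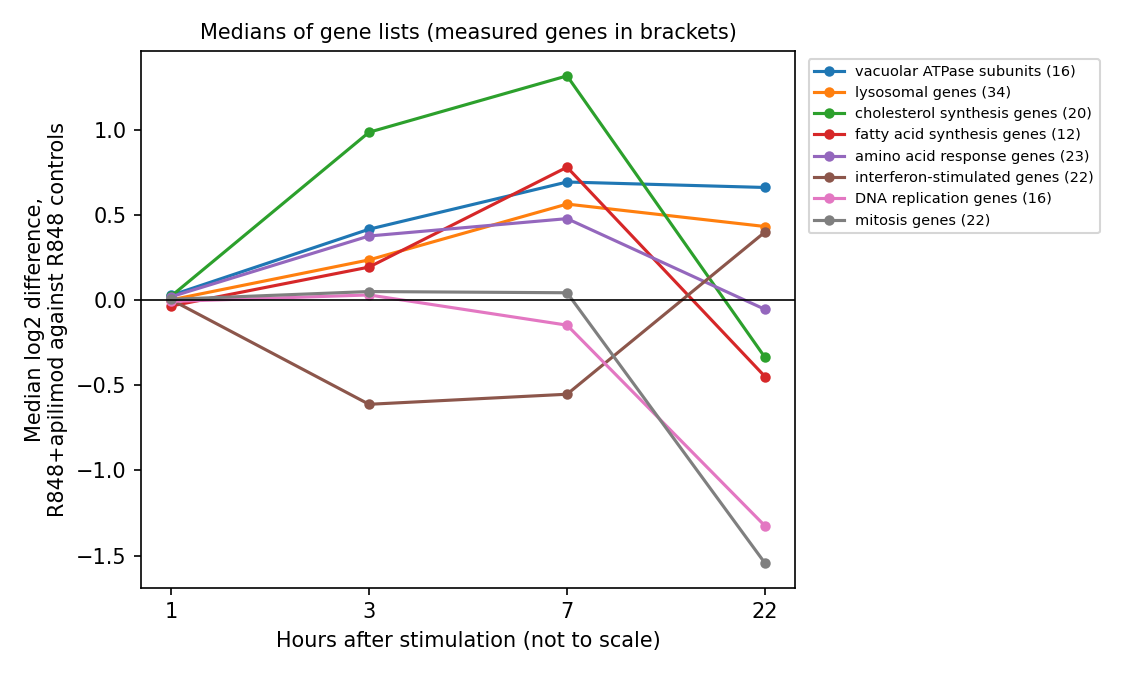
Median log2 difference of R848+apilimod against the R848 controls (y axis) over the measured members of 8 fixed gene lists at 1, 3, 7 and 22 h (x axis). Lines join the 4 hours of a list. The median of the mitosis genes falls to -1.54 at 22 h, while that of the cholesterol synthesis genes is 1.32 at 7 h and -0.34 at 22 h.

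Interferon-stimulated genes and cell cycle genes were also among those changed by apilimod. Of 22 interferon-stimulated genes, 13 were lower at 3 h, 13 were lower and 1 higher at 7 h, and 11 were higher and 3 lower at 22 h (16, 16 and 1, and 14 and 3 adjusted over the list alone). Ifit1 fell by 2.29 ± 0.16 at 3 h and was higher by 1.02 ± 0.16 at 22 h, and the antiviral gene Rsad2 was higher by 2.74 ± 0.16 at 22 h. The camera test gave adjusted p = 1.15e-14, and adjusted p = 0.219 with an estimated correlation at 3 h. Of 15 immediate-early genes, 9 were lower and 2 higher at 3 h (9 and 3 adjusted over the list alone; adjusted p = 3.11e-05, and adjusted p = 0.346 with an estimated correlation). The phosphatase gene Dusp2 was at -1.55 and the mRNA decay factor gene Zfp36 at -0.93. Of 16 NF-kB response genes, 8 were lower and 1 higher at 3 h (10 and 1 adjusted over the list alone; adjusted p = 4.34e-05, and adjusted p = 0.244 with an estimated correlation). Nfkbiz was at -0.46, while Tnfaip3 was higher by 0.99. All 22 mitosis genes fell at 22 h (22 adjusted over the list alone; adjusted p = 5.21e-22, and adjusted p = 0.246 with an estimated correlation). Among them were the cyclin gene Ccnb2 at -2.03 ± 0.10 and the kinesin gene Kif20a at -2.02 ± 0.11. At 22 h 14 of 16 DNA replication genes fell, with Uhrf1 at -1.77 ± 0.08 and Rrm2 at -1.76 ± 0.09 (14 adjusted over the list alone; adjusted p = 1.35e-13, and adjusted p = 0.246 with an estimated correlation). Of the ribosome biogenesis genes, 11 of 18 fell (11 adjusted over the list alone; adjusted p = 3.95e-04, and adjusted p = 0.666 with an estimated correlation). Among 15 macrophage identity genes, 6 were lower and 1 higher at 7 h, with the Fc receptor gene Fcgr1 at -3.25 and the integrin gene Itgam at -2.20 (7 and 1 adjusted over the list alone; adjusted p = 8.68e-04, and adjusted p = 0.262 with an estimated correlation). With apilimod 0 of 6 T and NK cell markers passed at any hour, and of 5 neutrophil and mast cell markers 1 was lower at 7 h and 1 at 22 h.

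In all, apilimod changed 1128 genes at 3 h (622 higher and 506 lower), 2405 at 7 h (1202 and 1203) and 4232 at 22 h (2476 and 1756). Of the genes called at 3 h, 903 were also called at 7 h (880 with the same sign, 221 expected of independent lists) and 677 at 22 h (551 with the same sign, 389 expected). The hours 7 and 22 h shared 1445 (1264 with the same sign, 830 expected). These comparisons share no array, but their fits share 1 estimate of the spread, so the expected overlap is too low a reference. The R848+API09 array at 22 h, which had the highest 18S signal and the lowest upper quartile, was 1 of the 2 control arrays at 22 h. Without it the spread was smaller (median standard error 0.0814 in place of 0.110) and the counts were 1869 at 3 h (924 higher and 945 lower) and 4826 at 22 h (2327 higher and 2499 lower). With R848 alone as the control, 1529 genes were higher and 1744 lower at 22 h, so the excess of higher genes at 22 h rests on that array. With R848 alone, 22 mitosis genes and 14 DNA replication genes were lower at 22 h, and of the interferon-stimulated genes 9 were higher and 3 lower. The apilimod array at 22 h also stood out in control probe sets: its 18S signal of 9.45 lay above all medium arrays, and its 3' minus 5' log2 value of actin was 0.383, against 0.488 on the R848+API09 array at 22 h and 0.111 to 0.335 on the 16 others. With the 6 medium arrays as 1 group, which adds the spread of medium over the hours, the counts were 565 at 3 h and 1483 at 7 h.

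In the fit over all 4 hours, no gene passed for apilimod against R848 alone (limma, 4 arrays per arm; 0 of 12257, and 1590 at an unadjusted p under 0.05). Gpnmb differed by 1.78 ± 0.39, Atf3 by 1.46 ± 0.28 and Il1b by -3.59 ± 0.92, with adjusted p of 0.159, 0.147 and 0.159. Without the 1 h arrays, 481 genes passed. The camera test called the vacuolar ATPase subunits (adjusted p = 3.35e-14, and adjusted p = 0.295 with an estimated correlation), lysosomal genes (adjusted p = 3.04e-13, and adjusted p = 0.295 with an estimated correlation), cholesterol synthesis genes (adjusted p = 1.60e-06, and adjusted p = 0.577 with an estimated correlation) and amino acid response genes (adjusted p = 6.50e-06, and adjusted p = 0.540 with an estimated correlation) higher. It called mitosis genes (adjusted p = 9.70e-04, and adjusted p = 0.674 with an estimated correlation) lower. Of these lists fry called the vacuolar ATPase subunits and the lysosomal genes (adjusted p = 0.0414 for each). Camera at the preset correlation called further lists, among them DNA replication genes (adjusted p = 0.00234) and ribosome biogenesis genes (adjusted p = 0.00251), both lower. With an estimated correlation camera called no list in this contrast.

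The third comparison set the inactive compound against R848 alone at the same dose of R848 and the same hours. No gene passed for R848+API09 against R848 alone over the 4 hours (limma, 4 arrays per arm; 0 of 12257, and 182 at an unadjusted p under 0.05). Of 12057 unchanged genes in the simulation of this contrast, 608 fell under that level. The spread of this fit is shared by all arms and takes in R848 and apilimod effects that change with time. It may therefore be too wide to show a small effect of API09. With the 2 arms alone, paired by hour, 825 genes were under 0.05 and 0 passed (limma). In the fit of all arms Il12b differed by 0.06 ± 0.18 (95% interval -0.32 to 0.44), Il1b by 0.05 ± 0.92 (-1.93 to 2.04), Gpnmb by 0.09 ± 0.39 (-0.77 to 0.94) and Atf3 by 0.18 ± 0.28 (-0.42 to 0.77). Camera called 1 list, the 6 T and NK cell markers, higher, and fry called none (adjusted p = 0.987 for that list; camera, adjusted p = 0.0187, and adjusted p = 0.995 with an estimated correlation). Over the 17 measured genes of the fixed panel the differences ran from -0.11 to 0.18, and all 17 intervals held 0. The bounds lay a median of 0.222 from the estimate, and the intervals lay within 1 log2 unit of 0 for 12127 genes (98.9%). These are unadjusted 95% intervals of the mean difference over the 4 hours. Larger mean differences were excluded at that level for those genes only. A larger difference at a single hour was not excluded. Counting genes at least 1 log2 unit from the R848 array of the hour, the R848+API09 arrays had 0, 0, 1 and 6 such genes at 1, 3, 7 and 22 h. The R848+apilimod arrays had 1, 278, 551 and 588 and the medium arrays 51, 362, 681 and 734. The 2 medium arrays at 0 h had 0 such genes between them. At 22 h the R848+API09 array lay lower than the R848 array by a median of -0.12 log2 units over all genes, against -0.02 to 0.00 at the earlier hours.

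**Figure D4:**
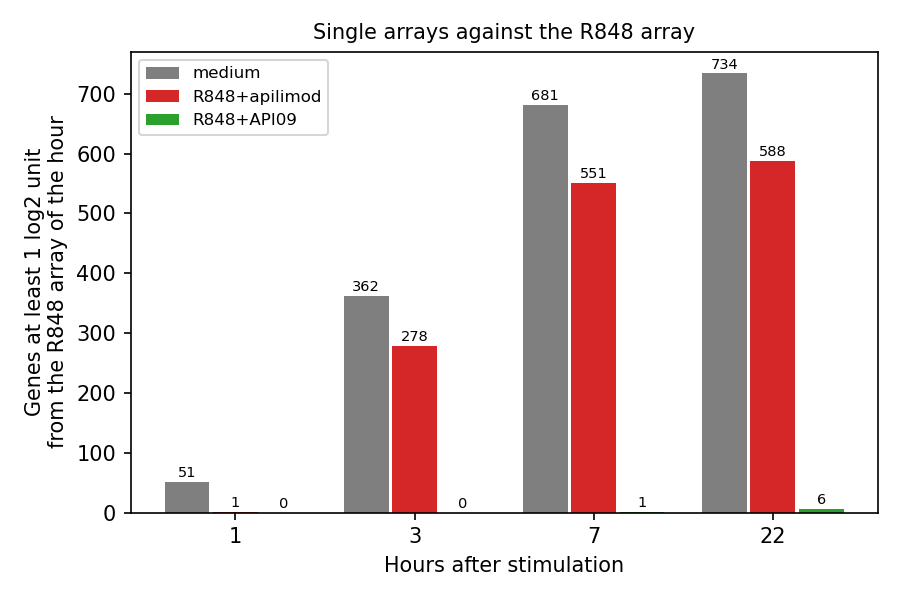
Number of genes at least 1 log2 unit from the R848 array of the same hour (y axis) for the single medium, R848+apilimod and R848+API09 arrays at 1, 3, 7 and 22 h (x axis). The R848+API09 arrays have 0 to 6 such genes, and the R848+apilimod arrays 278 to 588 from 3 h on.

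The compounds were then compared with each other. Within an hour, R848+apilimod against R848+API09 (1 array each, the spread from the R848 controls of all hours) gave 0 genes at 1 h (limma; 172 at an unadjusted p under 0.05), 889 at 3 h (520 higher and 369 lower), 2002 at 7 h (1048 and 954) and 4197 at 22 h (2805 and 1392). The excess of higher genes at 22 h rests on the R848+API09 array that stood apart, since the same apilimod array against R848 alone gave 1529 higher and 1744 lower. Genes lower with apilimod than with API09 were Il12b at -0.98 ± 0.14 (95% interval -1.28 to -0.68) at 3 h and -0.84 ± 0.14 (95% interval -1.14 to -0.54) at 7 h, Il6 at -2.36 ± 0.12 (95% interval -2.62 to -2.09) at 7 h and Il1b at -5.75 ± 0.19 (95% interval -6.18 to -5.33) at 3 h. Gpnmb was higher by 3.04 ± 0.11 (95% interval 2.79 to 3.28) at 22 h and Atf3 by 2.28 ± 0.16 (95% interval 1.92 to 2.64) at 7 h. The difference of Il12b at 22 h was -0.01 ± 0.14 (95% interval -0.31 to 0.29) and did not pass. Over all 4 hours, 0 genes passed (limma, 4 arrays per arm; 1612 at an unadjusted p under 0.05), and 543 did without the 1 h arrays. In that fit Gpnmb differed by 1.69 ± 0.39 (95% interval 0.84 to 2.54), Il12b by -0.45 ± 0.18 (-0.84 to -0.07) and Il1b by -3.64 ± 0.92 (-5.63 to -1.66). The vacuolar ATPase subunits (adjusted p = 1.97e-13, and adjusted p = 0.224 with an estimated correlation) and lysosomal genes (adjusted p = 5.63e-13, and adjusted p = 0.224 with an estimated correlation) were called higher by camera, and also by fry (adjusted p = 0.0290 for each). Of the other lists fry called LXR target genes lower (adjusted p = 0.0343) and phosphoinositide enzymes higher (adjusted p = 0.0492). Camera at its preset correlation called both (adjusted p = 0.0238 and 0.00638), and with an estimated correlation it called neither (adjusted p = 0.224 and 0.323). At the preset correlation camera also called further lists, among them cholesterol synthesis genes higher (adjusted p = 1.44e-06) and mitosis genes lower (adjusted p = 0.00275). With an estimated correlation camera called no list in this contrast.

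The fourth comparison asked whether the apilimod effect differed between late (7 and 22 h) and early hours (1 and 3 h). The difference passed for 2168 genes (1209 more positive late and 959 more negative). Of 17 fixed genes, 9 passed. The late effect was higher for Gpnmb by 2.19 ± 0.10, Cxcl10 by 0.80 ± 0.11, Tnf by 0.64 ± 0.11, Il23a by 0.50 ± 0.10 and Atf3 by 0.49 ± 0.14. It was lower for Il10 (-5.02 ± 0.09), Il6 (-0.87 ± 0.10), Ccl5 (-0.76 ± 0.10) and Il1b (-0.58 ± 0.17). The early mean takes in the 1 h arrays, where no gene passed, so an effect already full at 3 h comes out as stronger late. For Il1b the fall at 3 h was larger than at 7 or 22 h, so its lower late effect comes from the 1 h arrays. The fall of Ccl5 and the rise of Atf3 were also smaller at 22 h than at 3 h. Of the vacuolar ATPase subunits 13 of 16 had a higher late effect, and 20 of 22 mitosis genes and 13 of 16 DNA replication genes a lower one (14, 22 and 15 adjusted over the list alone). The camera test gave adjusted p = 4.51e-10, and adjusted p = 0.231 with an estimated correlation for the pump and adjusted p = 2.07e-18, and adjusted p = 0.231 with an estimated correlation for mitosis. Without the R848+API09 array at 22 h the count was 3335 (1625 more positive and 1710 more negative), with R848 alone as the control 1506 (715 and 791), and with the medium arrays as 1 group 1057, so the balance of directions rests on that array. Of the fixed genes, Atf3 did not pass with R848 alone as the control (0.40), nor Il1b with R848+API09 alone (-0.41).

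The last comparison asked which genes that R848 induced were lower with apilimod than with API09. R848 against medium and apilimod against API09 share no array. Within an hour, however, both come from 1 fit with 1 spread per gene, so genes of low spread are called in both and the overlap expected of independent lists is too low a reference. In the fits over all hours the count was 0 of 99 induced genes, since 0 genes passed for apilimod against API09 (limma), and it was 52 without the 1 h arrays. Within single hours, a comparison chosen after the values were seen, 199 of 643 induced genes were lower with apilimod at 3 h, against 19.4 expected of independent lists, and 86 were higher, against 27.3. At 7 h 424 of 1211 induced genes were lower (94.3 expected) and 214 higher (103.5 expected). At 22 h 328 of 1776 were lower (201.7 expected) and 557 higher (406.4 expected). Il1b, Ccl5 and Socs3 were among the induced genes, and with apilimod Socs3 was lower than in the R848 controls at 7 h (-1.71 ± 0.10) and 22 h (-2.78 ± 0.10). Genes that R848 lowered were also found among those higher with apilimod, 109 of 833 at 3 h (35.3 expected), 224 of 1829 at 7 h (156.4 expected) and 620 of 2444 at 22 h (559.3 expected). Lower still with apilimod were 30 at 3 h (25.1 expected), 154 at 7 h (142.4 expected) and 468 at 22 h (277.6 expected). All of these counts at 22 h rest on the R848+API09 array that stood apart.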

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

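The tests on lysosomal and vacuolar ATPase genes and on osteoclast genes, and the splits that keep 1 array of each arm at every hour, were chosen after the result was seen.

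The apilimod effect differed between late and early hours for 2168 genes, a difference between groups of time points by its own test. Among the fixed genes the late effect was higher for Gpnmb (2.19), Cxcl10 (0.80), Tnf (0.64), Il23a (0.50) and Atf3 (0.49). It was lower for Il10 (-5.02), Il6 (-0.87), Ccl5 (-0.76) and Il1b (-0.58). The early mean takes in the 1 h arrays, where no gene passed, and the fall of Il1b was in fact largest at 3 h. In probe sets that the comparisons do not use, the 18S ribosomal RNA signal lay above the 6 medium arrays (at most 9.36) on the R848+API09 array at 7 h (10.14), the R848+apilimod array at 22 h (9.45) and the R848+API09 array at 22 h (10.53).

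The R848+API09 array at 22 h stood apart from the R848 array at 22 h, with 6 genes at least 1 log2 unit away and a median shift of -0.12. A weak apilimod-like action of API09 was tested with the apilimod differences at 7 h. The differences of API09 from R848 at 22 h had a Pearson r of 0.0117 with them across 12257 genes. They thus show no likeness to the apilimod effect at 7 h. This cannot decide on an action like that of apilimod at 22 h, since the cholesterol synthesis and interferon-stimulated genes turned between those hours. A brightness difference of the array could also hide a weak effect. For an API09 effect already present at 7 h the r was 0.0590 across the same genes, which are not independent replicates. The differences at the 2 hours thus show little likeness. This cannot decide on a small effect at 7 h, since noise between single arrays would also give a low r. The API09 differences at 7 h had a standard deviation of 0.132, against 0.0937 between the medium arrays at 0 h. An array-wide trend with intensity cannot be told apart from changes of single genes, since 66.7% of these genes (4 of 6) stayed at least 1 apart after the trend was removed, between the bounds set for either reading, and 6 genes are few. A late action of API09 stays open, whether or not it is like that of apilimod at 22 h. A difference in RNA quality or labelling also stays open. The 3' minus 5' log2 value of actin was 0.488 on the R848+API09 array at 22 h, 0.383 on the R848+apilimod array at 22 h and 0.111 to 0.335 on the others. That of Gapdh was -0.131, within the range of the others (-0.173 to -0.104, and -0.0928 on the R848+apilimod array at 22 h).

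No gene passed for apilimod at 1 h (limma; 165 at an unadjusted p under 0.05), while 1128 did at 3 h. To test an exchange of the apilimod and API09 arrays at 1 h, the API09 differences at 1 h were set against the apilimod effect at 3 h. Their Pearson r was -0.0366 across the 1128 genes called at 3 h. This cannot decide, since exchanged arrays would also give a low r if apilimod did little by 1 h. The apilimod differences at 1 h had an r of 0.212 with the apilimod effect at 3 h, which lies between the bounds set before. A small early form of the effect below the threshold may thus be present but is not shown. Both compare 1 array at 1 h with the R848 array of that hour.

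Lysosomal and vacuolar ATPase genes were higher with apilimod at 22 h. A shift of bright genes is argued against for both lists: the median of the 34 lysosomal genes and that of the 16 pump subunits had a percentile of 100 among random lists matched on expression, also with R848 alone as the control. An osteoclast-like change of the cells cannot be told apart from other causes. Of 8 osteoclast genes outside these lists 4 passed higher (Ctsk 2.63, Dcstamp 1.41, Acp5 0.38 and Itgb3 0.36) and Mmp9 passed lower (-2.45). Their median was 0.27, and 3 of the 8 lay below 0. These values met the bounds written for a reading against such a change. A further condition, that no member pass higher, was not part of those bounds and was not met. As the genes moved both ways, no conclusion is drawn. A response of lysosomal genes to the inhibition of PIKfyve remains a candidate explanation, found and tested on the same arrays and not tested apart from other actions of apilimod.

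Other splits of the same 8 arrays into 4 and 4 were counted for each contrast over the hours, 35 splits each. For R848 against medium, 2 of the 35 splits gave at least the 124 genes of the real one, so by the 5% bound set before chance was not excluded. The other split, with the R848 array at 22 h and the medium array at 1 h exchanged, gave 458 genes, for a cause that was not tested. It leaves hours without an array of each arm, as do most of the 35 splits, so their share is no sound measure of chance. Among the 8 splits that keep 1 array of each arm at every hour the highest other gave 1 gene, and 8 splits are too few for a share under 5%. For apilimod against R848 alone, apilimod against API09 and R848-induced genes lower with apilimod than with API09, the real count was 0 and the highest other 0. For API09 against R848 alone the real count was 0 and the highest other, with the R848+API09 arrays at 7 and 22 h and the R848 arrays at 1 and 3 h exchanged, was 74. Another split gave 53. These splits also leave hours without an array of each arm, and the cause of their counts was not tested. For these 4 results all 35 splits give at least 0 genes by definition, so the splits say nothing about chance. At an unadjusted p under 0.05 (limma) the real counts were 1590 for apilimod and 182 for API09 against R848 alone, and 1612 for apilimod against API09. With the R848+API09 and R848 arms alone, paired by hour, the count for API09 was 825 in place of 182.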

How the results depend on the processing

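The overlap and the camera tests within single hours, the lists at 22 h with R848 alone as the control and, in the fits over all hours, the omission of the R848+API09 array at 22 h were chosen after the values were seen. The other alternatives were fixed before the data were examined. Of 242 counts for 14 results under an alternative, 207 were taken as staying within 1.5 times the count reported and 35 were not. The 207 include results in which no gene passed, such as API09 against R848 alone, where no ratio applies. Leaving out the first or the second medium array from before stimulation gave the same count for every result. These settings are thus a single check counted more than once, and the 207 overstate the stability. Requiring an absolute log2 difference of at least 1, which removes small changes by construction, left 71 genes for R848 against medium over all hours, and 52, 364, 696 and 849 for R848 at 1, 3, 7 and 22 h. For apilimod at 3, 7 and 22 h it left 271, 550 and 607, and 231 for late against early. With the 6 medium arrays as 1 group, the counts were 2990 for R848 at 3 h, 565 and 1483 for apilimod at 3 and 7 h, and 1057 for late against early. By construction this setting adds the spread of medium over the hours and sets R848 against 6 arrays. R848 against medium over all hours was the least stable count: 203 with quantile normalization, 62 with no filter, 208 with the stricter filter, 5 with the 2 arms alone paired by hour and 7 with no hour block, against 124. The cause was not tested, except that the filters change the number of genes tested (18193 with none and 7456 with the stricter one). Trend and robust variances called 1 gene for apilimod at 1 h. The cause was not tested.

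Leaving out arrays moved the counts of R848 against medium from 14 to 1162 and, with fewer arrays in the fit, those of apilimod against R848 alone from 0 to 481, of apilimod against API09 from 0 to 543, and of R848-induced genes lower with apilimod from 0 to 52, each highest without the 1 h arrays. The ranges were 63 to 128 for R848 at 1 h, 1274 to 3028 at 3 h, 796 to 1869 for apilimod at 3 h and 1629 to 3335 for late against early, each highest without the R848+API09 array at 22 h. For R848 at 7 and 22 h they were 2866 to 5037 and 5066 to 5784, for apilimod at 7 and 22 h 1802 to 3536 and 3715 to 4826. For API09 against R848 alone and apilimod at 1 h every count was 0. R848-induced genes lower with apilimod numbered 199, 424 and 328 within 3, 7 and 22 h and 0 at 1 h. Both the spread and the effect tested differ there, and the cause was not tested.

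For 163 values of named genes, 2759 recomputed values gave 2613 with the direction and side of the threshold reported, 137 that no longer passed, 5 that newly passed and 4 of opposite sign. With R848+API09 alone as the control, Il12b for apilimod at 22 h turned from 0.01 to -0.0103, and with quantile normalization Tfeb for apilimod at 22 h turned from 0.05 to -0.0259. For API09 against R848 alone, leaving out arrays moved Il12b from -0.0206 (without the 7 h arrays) to 0.149 and Il1b from -0.0843 (without the 1 h arrays) to 0.162. None of these passed, and the cause was not tested. For 42 list tests, 17 recomputed values kept their side of the threshold and 37 lost it. Signal over background limits dim genes: the stricter filter left 151 of the 163 named values.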

Other observations

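The genes and lists on medium over time, the choice among the other lists under R848, and the distances with medium subtracted, were chosen after their values were seen. Medium alone changed over the course: against the 2 arrays at 0 h, the medium array at 22 h had 1368 genes higher and 1327 lower at an adjusted p of 0.05 (limma), against 30 and 15 at 1 h, 63 and 56 at 3 h and 17 and 25 at 7 h. Among the 8 largest rises at 22 h were the stress gene Ddit4 (2.72 ± 0.17, log2 difference and its standard error), the glutathione-degrading enzyme gene Chac1 (2.48 ± 0.14) and the cystathionine gamma-lyase gene Cth (2.21 ± 0.09), and the 2 largest falls were of Pmepa1 (-2.80 ± 0.12) and Fos (-2.41 ± 0.15). Of 23 amino acid response genes, 21 were higher (median 0.89; camera, adjusted p = 1.09e-20, and adjusted p = 0.122 with an estimated correlation). Of 15 immediate-early genes 10 were lower and 1 higher, of 15 unfolded protein response genes 7 were lower, and of 18 ribosome biogenesis genes 9 were lower. Of 16 DNA replication genes 8 were lower, of 22 mitosis genes 9 were lower, of 10 oxidative stress response genes 6 were lower and 1 higher, and of 21 oxidative phosphorylation genes 8 were higher. Comparisons at 22 h against medium therefore set R848 against medium-treated cells that had themselves changed since 0 h.

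Other lists under R848 also held called genes. Of 13 p53 and apoptosis genes, 8 were higher and 3 lower at 3 h, with the death receptor gene Fas at 3.26 and the stress gene Gadd45b at 3.22 (adjusted p = 2.54e-04, and adjusted p = 0.251 with an estimated correlation). Of 15 macrophage identity genes, 9 were higher and 3 lower at 22 h, with the integrin gene Itgam at 2.46 and the scavenger receptor gene Msr1 at 2.48 (adjusted p = 0.0118, and adjusted p = 0.512 with an estimated correlation). Of 10 oxidative stress response genes, 9 were higher and 1 lower at 22 h, with Slc7a11, the cystine transporter gene, at 2.91 and Hmox1 at 2.35 (adjusted p = 1.61e-05, and adjusted p = 0.314 with an estimated correlation). Of 12 regulators of the IL-12 genes, 7 were higher and 1 lower at 7 h, with Maf at 4.39 and Bcl3 at 3.53 (adjusted p = 2.04e-05, and adjusted p = 0.170 with an estimated correlation).

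One hypothesis was that apilimod delays the R848 response, so that the apilimod array at 22 h would lie closer to the R848 array at 7 h than to that at 22 h. Over 7049 genes called for R848 at any hour, the root mean square log2 distance was 0.966 to the R848 array at 7 h and 0.590 to that at 22 h, a ratio of 1.64. Arrays of the same hour share the changes of time in culture, which lowers the distance at 22 h with or without a delay. With the medium array of the hour subtracted the distances were 0.839 and 0.590, a ratio of 1.42, which adds the noise of the medium arrays at 7 and 22 h to the first distance. The ratio with medium subtracted argues against a response held at its 7 h state. A shorter delay, a delay of single genes, and changes of time in culture that differ under R848 stay open.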
